A study of Danio rerio with 6 samples.

How the data were processed

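Messenger RNA was measured in whole brains of female zebrafish (AB strain) at 12 months of age, 1 brain per array, on one-colour oligonucleotide arrays labelled with Cy3. Per the labels' protocols, embryos were held in lead acetate at 100 ppb, or at 0 ppb for controls, from before 2 hours until 72 hours after fertilization and were then raised without lead. Each group has 3 fish. Males, which the series description also mentions, were not analysed here.

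The authors deposited 1 table per array with an RMA intensity for each target, a target being a transcript or expressed sequence covered by up to 3 probes. Per the submitters' processing notes these intensities were made with RMA, whose version is not stated, and the values are on a linear scale. How many arrays were normalized together is not stated. The same tables hold a score for the standard error of each target, per the file headers, which was not used in any test. The authors also deposited a table of 113549 probe intensities per array and 27114 random control probes per array. These probe intensities shared the same median on every array, 1194.71. Between 62.0% and 70.3% of the deposited target intensities lay within 0.1 log2 of the median of their own probes. A further table by the authors lists 94 altered targets with a signed fold score (lead over control, or minus control over lead), a log2 ratio and a p-value, per the file headers. The test behind it and any adjustment are not stated in it, so the authors' p-values serve only to describe that table.

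Control features were left out and log2 was taken of the deposited target intensities, with no filter and no added constant. This gave 38489 targets, of which 15667 were paired with 1 of 11541 gene symbols through RefSeq names or symbols in the files. Of 3055 RefSeq targets 2663 matched the reference table, which belongs to the assembly GRCz12tu and was used for names only. A further 8296 targets carried only the name of a homologue in another species, and 14526 carried neither. Coordinates are those of the files, on the Zv7 assembly by their scaffold names, except those of targets named OTTDART. Of pairs of targets with one name and chromosome, 96.7% lay within 100000 bases among OTTDART targets and 94.5% among the others, but 1.82% across these sets, so OTTDART coordinates belong to an assembly that is not given. A scaffold name stands in place of a chromosome where a target is not placed. The median target intensity was 2100 to 2211 per array. The 95th percentile of the random control probes, used as background, was 948 to 1312 per array, and 59.8% to 66.7% of targets lay above it. For arrays, the number of fish limits the precision. The median standard error of a log2 change was 0.18.

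Lead was compared with control target by target with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderated test, two-sided), with Benjamini-Hochberg adjustment over all targets and a threshold of 0.05. Single probes were tested in the same manner. Before the data were examined, 29 gene lists were fixed, covering neural cell types and signalling, stress and metal handling, cancer genes and markers of other tissues that a dissected brain can carry. A gene with several targets was represented by the target with the highest mean over all arrays. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, and with camera at a correlation estimated from the data. The fry test asked whether the genes of a list move one way, without a comparison to other genes. Each was adjusted over the 29 lists. The separation of the groups was measured as the ratio of the mean Euclidean distance between groups to that within groups, with an exact permutation test over the 10 splits of the 6 arrays. The tests were tried before use on simulated data for lead against control, with 38489 targets and 50 changed at each size. The limma test recovered 0% of those changed 1.5-fold, 22% at 2-fold, 50% at 3-fold and 80% at 4-fold, with 6 false among 82 calls. Of 29 simulated lists over 11541 genes, camera called 2 of 2 shifted ones and 0 others. The simulated genes were independent of each other. In the real lists the estimated correlation was 0.26 for erythrocyte, 0.22 for cell cycle and 0.60 for cilia genes. The simulation therefore does not tell how often camera at the preset correlation calls lists of correlated genes falsely. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

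The genes named were set by a rule, also fixed before the data were examined. It took up to 12 genes per direction with the largest change among those past the adjusted threshold. Failing these, it took those with an unadjusted p under 0.01 and groups that do not overlap. It added the members of each described list with the smallest p, the 5 highest and 5 lowest entries of the authors' table, and the 3 members with the highest level in each list of another tissue. At most 2 targets without a symbol were named per direction. Single genes that the rule or a marker list would name but that are withheld are not reported here. Where every array of 1 group lay under the random probes, a change is given as a bound against that background. Where both groups did, the report gives no fold.

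The alternatives tried were other scalings of the arrays (quantile normalization again, or centring on the median), 3 filters on dim targets, a floor, other summaries of probes into targets and of targets into genes, a trended robust prior, array weights, a test without moderation, other thresholds, the replicate number as a block, and leaving out each array in turn. Lists of marker genes for cerebellum and adult globins were written before their tests. A list of inner ear and cartilage genes, and the set of all measured hox genes, were written after some of their members had been seen.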

Results

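The data are target intensities from 6 arrays, 3 brains of females exposed as embryos to 100 ppb lead and 3 brains of control females, all taken at 12 months of age. The comparison asks whether exposure to lead in the first 72 hours of development is followed by differences in gene expression in the aged female brain. All changes below are lead minus control on the log2 scale with their standard error, and n = 3 brains per group throughout.

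Brains of lead-exposed fish had higher signal from a list of cell cycle and neurogenesis genes and lower signal from genes of red blood cells. Each was taken as a list against all other genes at a preset correlation. Neurogenic members measured in the first list lay between −0.06 and 0.30 where above the random probes on every array. Targets that the authors' table of altered targets names NEUROD1 and NEUROD2 were not paired with these symbols here and lay at 0.88 and 0.99. With a correlation estimated from the data neither list passed (adjusted p = 0.715 for each in limma camera). Among the genes with large single differences were higher values of the neural transcription factors pax6b and pax6a, and lower values of red cell genes such as nt5c2l1 and alas2. No single gene passed adjustment for all targets. In limma, 0 of 38489 targets had an adjusted p under 0.05, and the ordinary test without moderation also gave 0. At an unadjusted p under 0.05 there were 1696 targets (990 higher, 706 lower) in limma and 1655 in the ordinary test, where 1924 would come by chance if nothing differed. Single probes gave 0 past adjustment and 4861 of 113549 at an unadjusted p under 0.05 in limma, where 5677 would come by chance. The 2 groups did not overlap in 3653 targets, or 9.49%, where chance gives 10% for 3 against 3. Of all targets, 96.1% differed by less than 1.5-fold. The count of 1696 was 3098 without control replicate 2, 1075 without control replicate 3 and 1063 without lead replicate 1. Its balance turned too, with 672 higher and 760 lower without control replicate 1, 490 and 585 without control replicate 3, and 960 and 1094 without lead replicate 2, while centring on the median gave 1127 and 624.

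Among genes with a symbol, an unadjusted p under 0.01 and groups that do not overlap, the 12 per direction with the largest differences all missed the adjusted threshold in limma (adjusted p = 0.958 for each). Values of pax6b, a regulator of neural progenitors and of the eye, were 1.73 ± 0.36 higher (target OTTDART00000022987, chromosome 7, 6303242 to 6310127), from a mean intensity of 4061 to 13513. Its paralog pax6a stood 1.28 ± 0.27 higher (OTTDART00000024640, chromosome 25, 10822525 to 10833232). For both genes the target with the highest mean, which represents the gene in lists, differed less and is given with the axon guidance list below. The secreted neural protein gene olfm2b was 1.23 ± 0.31 higher, at intensities of 11114 and 25998. The neuronal membrane protein gene lingo4a was 1.16 ± 0.32 higher, and ube2c, which serves the exit from mitosis, was 1.02 ± 0.18 higher. Values of the muscle calcium genes cacng1b and casq2 were 1.36 ± 0.32 and 1.33 ± 0.32 higher. The other higher genes were bnip4 (1.77 ± 0.43), cd9r (1.1 ± 0.25), HYAL4 (1.03 ± 0.28) and zgc:154142 (1.00 ± 0.24). For ighv4-5 the controls and 2 of the 3 lead arrays lay under the random probes, and its value was at least 1.19-fold higher, which rests on lead replicate 1. Among the lower genes, the nucleotidase gene nt5c2l1 was at −1.88 ± 0.49 (OTTDART00000028376, chromosome 10, 10276657 to 10281104), from an intensity of 3563 to 969. A further target of nt5c2l1 was at −1.06. A target of alas2, the erythroid enzyme that starts heme synthesis, stood at −1.43 ± 0.39 (OTTDART00000013156). The copper transporter gene atp7a was at −1.02 ± 0.25 (NM_001042720, Zv7 chromosome 14, 19180840 to 19219506), from 5712 to 2815. The neuropeptide Y receptor gene npy7r was at −1.05 ± 0.29. Only 1 of the 3 control arrays lay above the random probes for bnip4 and casq2, and only 1 of the 3 lead arrays for nt5c2l1, alas2 and npy7r, so the sizes of these differences are not well measured. Phosphate carrier slc20a1a was at least 2.25-fold lower, the ammonium channel gene rhag at least 1.48-fold, si:dkey-106c17.2 at least 1.39-fold and nmt1b at least 1.11-fold, since the lead group lay under the random probes for each. The remaining lower genes were si:ch211-250g4.3 (−1.72 ± 0.46), si:dkey-63j12.4 (−1.09 ± 0.15), the erythroid regulator klf1 and the globin hbae4. For klf1 only 1 control array and no lead array lay above the random probes, so no fold is given. The globin hbae4 lay under them in both groups.

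The target closest to the threshold has no gene name. ENSDART00000077505 (Zv7 chromosome 19, 34497097 to 34524177) was at −1.66 ± 0.13, with log2 values of 11.86 to 12.06 in controls and 10.20 to 10.40 in lead brains, of which 2 of the 3 lay above the random probes, and an adjusted p of 0.152 in limma. A count limited to targets above the median intensity put it past the threshold, at an adjusted p of 0.0380. The transcripts ENSDART00000077550, ENSDART00000077610 and ENSDART00000077480 overlap it, were looked up after it was seen, and stood at −1.76, −1.46 and −1.18. The other targets without a symbol named by the rule were ZV700S00005148 (−1.33 ± 0.18), ZV700S00000104 (0.74 ± 0.13) and ZV700S00002719, which lay under the random probes in both groups.

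**Figure D1:**
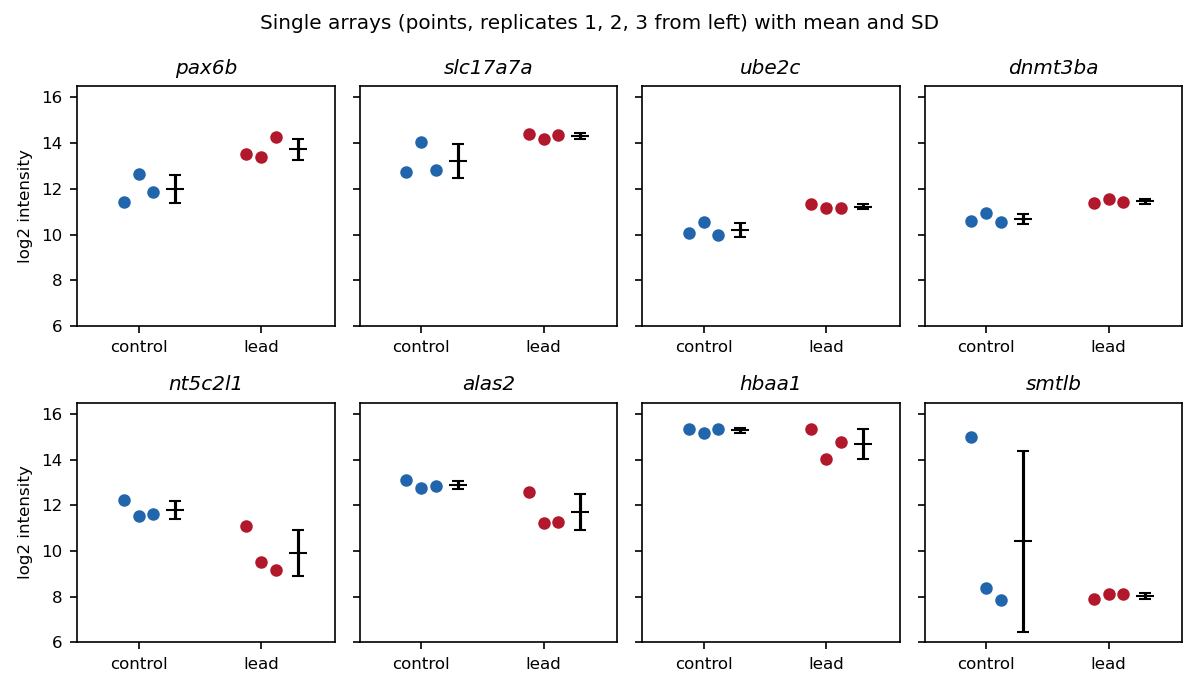
Log2 intensity of 8 genes on each array, controls in blue and lead in red, with the group mean and SD beside the points. pax6b, by its target with the largest change, slc17a7a, ube2c and dnmt3ba lie higher and nt5c2l1 and alas2 lower on every lead array than on every control array, hbaa1 overlaps, and smtlb is high on control replicate 1 alone.

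As a list, the cell cycle and neurogenesis genes were higher in lead brains (limma camera, preset correlation, adjusted p = 1.63e-07; adjusted p = 0.715 with an estimated correlation). Of the 69 genes fixed for the list, 30 were measured under a symbol. Of 30 measured genes, 27 were higher, with a median of 0.31, and 8 had an unadjusted p under 0.05. Of these genes, 1 passed when adjusted over the list alone and 0 over all targets. Of the 30 in the list, 11 lay above the random probes on every array, and among the 8 only mcm3 did. Among its members with the smallest p, the mitotic gene ube2c and the cyclin gene ccna2 (0.64 ± 0.20) lay above the random probes on 5 and 4 of the 6 arrays. The neurogenic insm1a and the mitotic kinesin kif23 lay under the random probes in both groups, as 13 of the 30 genes did on every array. Values of mcm3, a helicase subunit for DNA replication, were 0.47 higher, while pcna was 0.16 higher. Measured neurogenic members above the random probes on every array were sox4a (0.07), sox11a (0.30), sox11b (−0.06), ascl1a (0.09), stmn1a (0.12) and tubb5 (0.04). Some fixed genes were missed because their targets were not paired with the symbol. The authors' table names such targets NEUROD1 (0.88), NEUROD2 (0.99), TOP2A (0.64), KIF11 (0.77) and MCM2 (0.70). It holds altered targets only, so it does not show fixed genes that were missed and did not differ. The list held its call without each of the 6 arrays, and lost it when targets below the median intensity were left out (adjusted p = 0.0866). Median deviations from the 6-array mean were −0.23, −0.04 and −0.26 in the controls and 0.16, 0.26 and 0.00 in the lead brains.

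Genes of chromatin and DNA methylation were also higher as a list (adjusted p = 0.00479 in limma camera; adjusted p = 0.715 with an estimated correlation). Of 37 measured, 30 were higher, with a median of 0.14. The de novo DNA methyltransferase genes dnmt3ba and dnmt3ab were at 0.77 ± 0.15 and 0.32 ± 0.14, the histone methyltransferase gene ezh2 at 0.48 ± 0.18, and uhrf1, needed for maintenance methylation, at 0.41 ± 0.15 with 3 of the 6 arrays above the random probes. Without lead replicate 2 the list did not pass (adjusted p = 0.214).

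Red blood cell genes were lower as a list (adjusted p = 1.04e-11 in limma camera; adjusted p = 0.715 with an estimated correlation). Of 20 measured genes 17 were lower, with a median of −0.69, and 12 of these had an unadjusted p under 0.05. When adjusted over the list alone 7 passed, and 0 over all targets. Of the 20 genes, 9 lay above the random probes on every array and 6 lay under them on every array. The list includes nt5c2l1, si:ch211-250g4.3, klf1 and rhag given above, the anion exchanger gene slc4a1a at −1.09 and the membrane skeleton gene epb41b at −1.33. Adult alpha globins hbaa1 and hbaa2 stood at −0.59 and −1.48, the beta globin ba1l at −0.79 ± 0.32, and the carbonic anhydrase gene cahz at −0.35 ± 0.24. The embryonic globin hbae3 went the other way, at 0.55. The median deviation of the list was 0.53, 0.25 and 0.39 in the controls and 0.12, −0.58 and −0.50 in the lead brains, so lead replicate 1 lay nearer to the controls. The call held without each of the 6 arrays.

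The ependyma and cilia list was higher (27 of 28 genes, median 0.25, adjusted p = 0.00431 in limma camera; adjusted p = 0.715 with an estimated correlation), with 0 genes at an unadjusted p under 0.05. Examples are foxj1a, the master regulator of motile cilia, at 0.85 ± 0.44, cfap52 at 0.95 ± 0.48, both above the random probes on 2 of the 3 control arrays, and ift88 at 0.30 ± 0.16. The median deviation was 0.69 in lead replicate 1 and between −0.27 and 0.08 in the other 5 arrays. Without lead replicate 1 the adjusted p was 0.872 and the direction turned, and without control replicate 1 it was 0.103.

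The pituitary (12 of 17 genes lower, median −0.25), vessel and meninges (28 of 38, median −0.16) and skin (23 of 31, median −0.12) lists were lower, each with an adjusted p of 0.0180 in limma camera and of 0.715 to 0.717 with an estimated correlation. In all of them control replicate 1 stood apart from the other arrays, with median deviations of 0.52, 0.54 and 0.43. The hormone genes smtlb, gh1 and pomca had log2 values of 14.98, 12.78 and 14.99 on that array. In the pituitary list the smallest p above the random probes was that of trhra (−0.25 ± 0.15). On the other 5 arrays smtlb lay between 7.88 and 8.40, gh1 between 7.44 and 8.12 and pomca between 11.92 and 12.95. Of the most abundant vessel genes, the glucose transporter gene slc2a1a was at 0.01 ± 0.13, dcn at 0.29 ± 0.34 and sparc at −0.27 ± 0.22. Of those of skin, krt8 was at −0.20 ± 0.31, icn at −0.25 ± 0.39 and krt18a.1 at −0.17 ± 0.36. Examples with smaller p were flt1 (−0.35 ± 0.18), krt97 (−0.57 ± 0.28) and krt17 (−0.32 ± 0.16), above the random probes on 2, 2 and 1 of the 3 lead arrays. Without control replicate 1 the adjusted p was 0.633, 0.633 and 0.980, and the vessel list turned upward. Each of these lists also missed the threshold without lead replicate 2.

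Activity-regulated genes (21 of 32 lower, median −0.21), glutamatergic synapse genes (23 of 31, median −0.11) and neuropeptide genes (33 of 45, median −0.08) were lower as lists, each with an adjusted p of 0.0180 in limma camera and of 0.715 with an estimated correlation. The neuronal activity genes fosab and npas4a were at −0.64 ± 0.33 and −0.88 ± 0.55, gadd45bb at −0.45 ± 0.22 with 1 of the 3 lead arrays above the random probes, and klf9 at −1.41 ± 0.77 with 2 per group above them. For npas4a the lead arrays stood at 14.44, 12.59 and 12.17 and the controls between 13.76 and 14.18. For klf9 the controls spread widely, at 9.56, 12.62 and 11.63, with the lead arrays at 10.45, 8.99 and 10.15. In the glutamatergic list the member with the smallest p was among the 8 that were higher: slc17a7a, the vesicular glutamate transporter, was at 1.1 ± 0.35, while slc17a8 was at −0.92 ± 0.55 and gria4b at −0.37 ± 0.23. The value of slc17a8 rests largely on control replicate 1, at 13.12, with the other arrays between 10.74 and 11.34. In the neuropeptide list pnocb was at −0.52 ± 0.25 and pcsk1, a prohormone convertase, at −0.39 ± 0.20. The activity list lost its call without control replicate 2, lead replicate 2 or lead replicate 3 (adjusted p up to 0.688), the glutamatergic list without control replicate 3, lead replicate 1 or lead replicate 3 (up to 0.358), and the neuropeptide list without control replicate 3 or lead replicate 3 (up to 0.649).

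**Figure D2:**
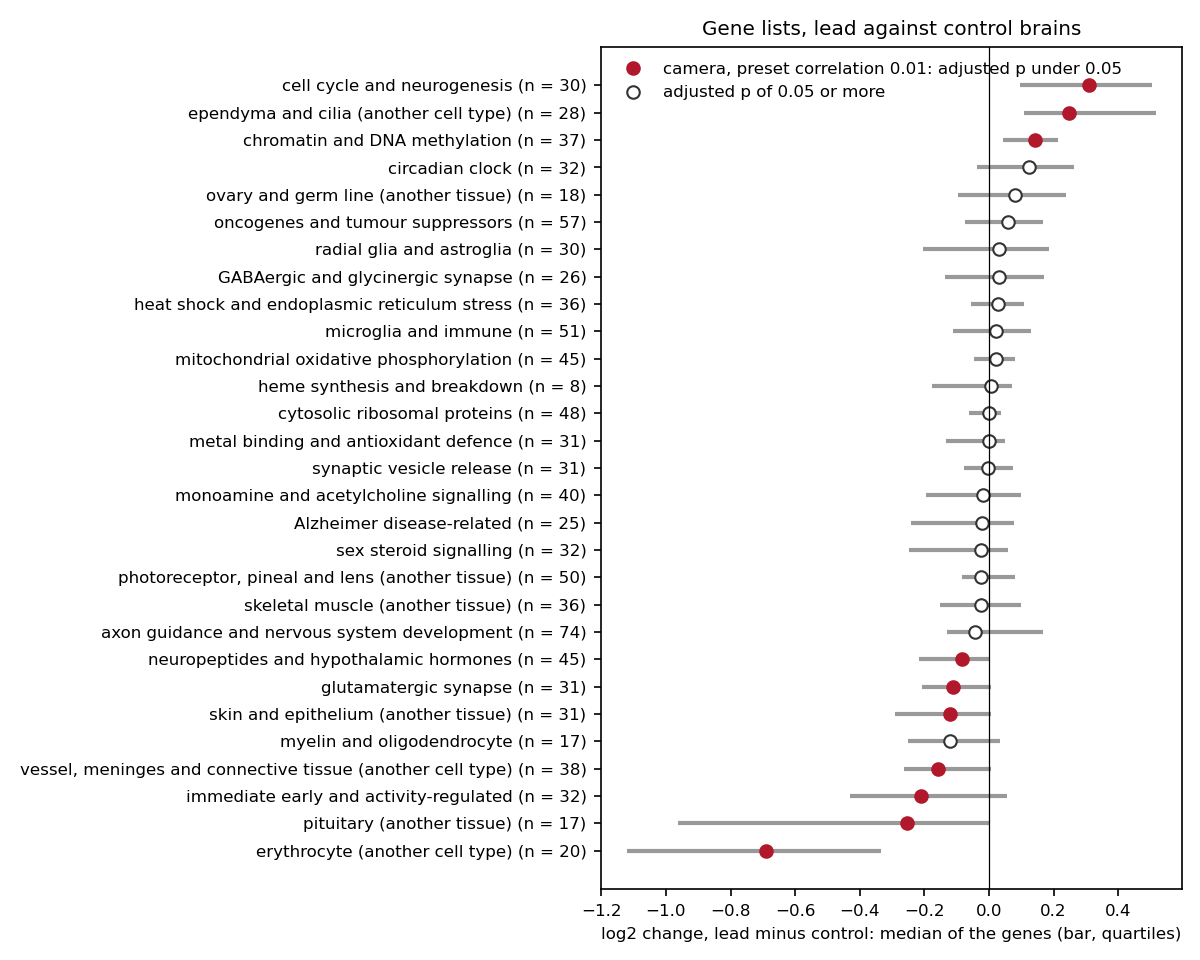
Median log2 change, lead minus control, of the measured genes of the 29 lists, with bars from the lower to the upper quartile. Filled points mark the 10 lists with an adjusted p under 0.05 in limma camera at a preset correlation of 0.01, none of which passed with an estimated correlation, from −0.69 for erythrocyte genes to 0.31 for cell cycle genes.

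**Figure D3:**
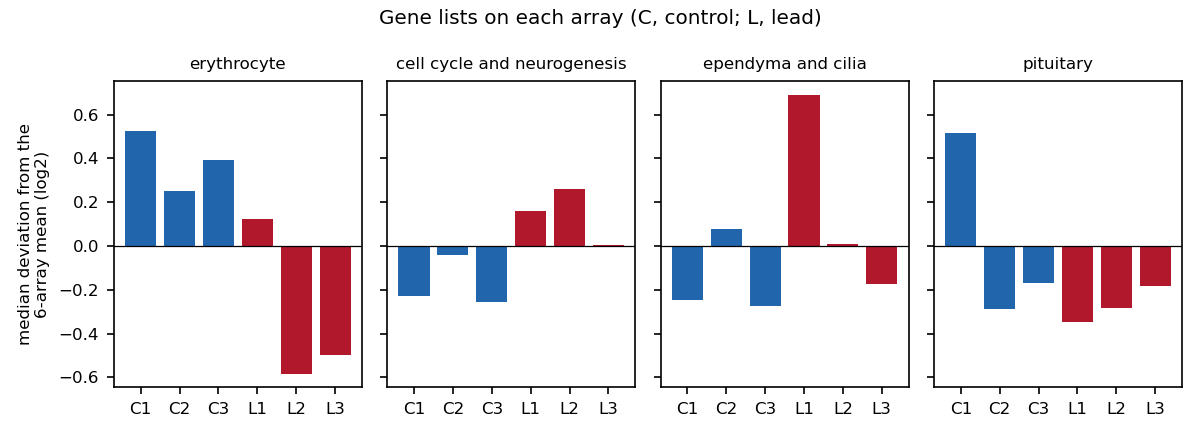
Median deviation of the genes of 4 lists from their mean over the 6 arrays, on the log2 scale, for control (C) and lead (L) replicates 1 to 3. Erythrocyte genes are lowest on lead replicates 2 and 3, cilia genes stand at 0.69 on lead replicate 1, and pituitary genes at 0.52 on control replicate 1.

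The other 19 lists did not pass in limma camera. Metal binding and antioxidant genes had a median of 0.00 and an adjusted p of 0.138, with the transferrin receptor gene tfr1a, above the random probes on 2 control arrays, at least 1.03-fold lower and gstm.1 at −0.67 ± 0.22. The heme list (8 genes, adjusted p = 0.374) had a median of 0.01, a mean of −0.14, alas2 (OTTDART00000025755) at −1.20 ± 0.37 and blvra at −0.20 ± 0.14. Axon guidance and nervous system development genes had an adjusted p of 0.699, with a median of −0.04 and a mean of 0.03. That list holds fgf8a at 1.29 ± 0.40, pax6a at 0.96 ± 0.29 and pax6b at 0.52 ± 0.18. These values of pax6a and pax6b are from their targets with the highest mean, other than the targets given above. Oncogenes and tumour suppressors (adjusted p = 0.699, median 0.06) hold mycn at 0.74 ± 0.18 and cdkn1ba at 0.44 ± 0.19. Alzheimer disease-related genes had an adjusted p of 0.109 and a median of −0.02, with ncstn at −0.29 ± 0.15 and prnpa at −0.35 ± 0.21. Myelin and oligodendrocyte genes had an adjusted p of 0.0741 and a median of −0.12, with erbb3b at −0.66 ± 0.25 and olig1 at −0.38 ± 0.20. This list passed with the replicate number as a block (adjusted p = 0.0499) and with quantile normalization again (adjusted p = 0.0498), and its adjusted p in limma camera went from 0.0127 without lead replicate 1 to 0.904 without lead replicate 2. The circadian list (adjusted p = 0.199, median 0.12) holds xpc at 0.48 ± 0.14, cry2 at 0.45 ± 0.14 and hlfb at −0.43 ± 0.14. The monoamine and acetylcholine list (adjusted p = 0.282, median −0.02) holds the receptor genes adrb1 at 1.25 ± 0.50 and drd3 at 0.42 ± 0.17. Sex steroid genes (adjusted p = 0.122, median −0.02) include hsd17b8, at least 1.07-fold higher with 1 lead array above the random probes, esr1 at −0.33 ± 0.15 and paqr6 at −0.35 ± 0.19. The microglia list (0.699, median 0.02) holds mhc2dab at −0.62 ± 0.30 and isg15 at 1.19 ± 0.60, and the radial glia list (0.95, median 0.03) s1pr1 at 0.23 ± 0.14 and fabp7b at 0.96 ± 0.57. The adjusted p was 0.699 for GABAergic and glycinergic synapse genes (median 0.03, gabbr2 0.33 ± 0.14, slc32a1 −0.19 ± 0.15), 0.465 for synaptic vesicle genes (median 0.00, syt5a −0.84 ± 0.31, syt1b −0.95 ± 0.40, syt2b −0.36 ± 0.19, sv2bb 0.39 ± 0.22), 0.732 for heat shock genes (median 0.03, sesn2 −0.26 ± 0.17, atf6 0.75 ± 0.53, hspe1 0.20 ± 0.15), 0.699 for oxidative phosphorylation (median 0.02, sdhda −0.40 ± 0.20, ndufb6 0.22 ± 0.12) and 0.365 for ribosomal proteins (median 0.00, rpl38 −0.27 ± 0.16, rpl32 −0.15 ± 0.12). The camera direction was down with a median above 0 for the metal, heme, ribosomal, GABAergic, oxidative phosphorylation, microglia and heat shock lists. Mean and median differed in sign for the metal, monoamine, ribosomal, heme, axon guidance, photoreceptor and radial glia lists. Among markers of other tissues it was 0.465 for ovary (median 0.08, with 16 of 18 genes under the random probes on every array), 0.465 for skeletal muscle (median −0.03, neb 0.52 ± 0.21, ryr1b −0.33 ± 0.21) and 0.699 for photoreceptor, pineal and lens genes (median −0.02, crybb1 0.38 ± 0.12, rpe65b 0.33 ± 0.20). Of the genes in this paragraph, mycn and crybb1 lay above the random probes on 5 of the 6 arrays and syt5a and fabp7b on 3. The difference of atf6 rests largely on control replicate 3, at 11.84, with the other arrays between 13.5 and 14.1. For syt1b control replicate 1 stood at 12.74 and the other arrays between 10.62 and 11.69.

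The authors' table of altered targets holds 94 entries, 66 higher and 28 lower after lead. Their 5 highest entries all carry the name PAX6, with signed folds of 2.786 to 3.327. Of these, 3 are targets of pax6b, and ZV700S00005507 and ZV700S00005508 lie at Zv7 chromosome 7, 8611744 to 8614259, which cannot be set beside the coordinates of the pax6b targets. The 5 lowest are GP1BB (−2.157), NMT1 (−2.056), ATP7A (−2.029), EPOR (−1.907) and KLF1 (−1.891). The authors' log2 ratios differed from those here by at most 0.00092, being taken from the same arrays. The same direction of all 94 was therefore given beforehand. All 94 had an unadjusted p under 0.05 in limma and groups that did not overlap, and 0 had an adjusted p under 0.05 over all targets (lowest 0.958). Adjusted over the entries alone 94 passed, which is not independent evidence because the entries were chosen on these samples. An ordinary test with an unadjusted p under 0.05 and at least 1.5-fold was met by 272 targets, 149 higher and 123 lower, with all 94 among them.

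Taken over all targets, the groups did not stand apart. The mean distance between arrays of different groups was 91.1 and within groups 92.3, a ratio of 0.987 (exact permutation test, p = 0.7, where the smallest p that 3 against 3 allows is 0.1). The first principal component held 32.6% of the variance with control replicate 1 at one end (−64.3) and lead replicate 2 at the other (40.5). By the deposited labels of the scan, the arrays of each group lay in a block of neighbouring positions, so position and group cannot be told apart.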

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

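The tests that left out 2 arrays together were chosen after the result was seen. In limma the count of targets past adjustment stayed at 0 without each array in turn, under both other scalings and under the remaining planned settings, with these exceptions: it was 1 with targets below the median left out (ENSDART00000077505, fewer targets tested) and 669 at an unadjusted p under 0.05 with at least 1.5-fold. It was 0 without control replicate 1 and lead replicate 1, and 0 without control replicate 1 and lead replicate 2. It was 1 without control replicate 1 and lead replicate 3 (NM_200406, adjusted p = 0.0348, picked out after its value was seen). That target stood at 14.76, 14.95 and 14.45 on control replicate 1 and lead replicates 1 and 2. On control replicates 2 and 3 and lead replicate 3 it stood at 7.74, 7.51 and 7.44. Leaving out the 2 arrays that differed from their own group thus made this call. Why the arrays differ was not tested. For probes the count was 3004 at the looser threshold, and 0 to 1 with 1 array left out, the 1 being a probe of ENSDART00000046844 without control replicate 2. The count of lists, 10 as reported, was 6 with targets below the median left out, 0 with an estimated correlation (lowest adjusted p = 0.715), 0 with fry (0.531), 7 to 11 with 1 array left out, 7 without control replicate 1 and lead replicate 1, 9 without control replicate 1 and lead replicate 2, and 6 without control replicate 1 and lead replicate 3. Lists that passed only in some settings were myelin (lowest adjusted p = 0.0127 and highest 0.929), sex steroid (0.00505 and 0.929), microglia (0.000921 and 0.929, with opposite directions without lead replicates 1 and 2), metal binding (0.0410 and 0.929) and axon guidance (0.0421 and 0.996). Correlations of same-numbered arrays were 0.31, 0.03 and −0.05. They gave no clear sign that the replicate numbers pair the fish, but 3 arrays per group are too few to exclude it. With a replicate block the counts were 0 targets (lowest adjusted p = 0.754), 0 probes, 11 lists with myelin added and 0 of the authors' entries. The series' probe values, averaged per target, also gave 0 of these entries. The separation of groups was 0.988 with arrays centred on their medians and 0.944 to 1.06 with 1 array left out, above 1 without control replicate 2 only. The scalings moved the median of all targets by at most 0.02. Of 1161 log2 changes of 86 named targets under the alternatives, 1138 kept their sign and 0 passed adjustment. As reported, those that turned lay between −0.27 and 0.20. Of these, fmoda and nanos3 lay under the random probes in both groups and foxl2a on every lead array, so their values show turns of sign and no change in level. With 1 array left out mylpfb ranged from −0.11 to 0.35, krt8 from −0.40 to 0.083, icn from −0.52 to 0.17, krt18a.1 from −0.44 to 0.17, slc2a1a from −0.072 to 0.078, nanos3 from −0.040 to 0.20, rom1a from −0.14 to 0.14, cfap20 from −0.019 to 0.21, sycp3 from −0.010 to 0.055, foxl2a from −0.0038 to 0.22 and tph2 from −0.049 to 0.36. The median of the probes gave −0.013 for tph2, −0.23 for fmoda, −0.013 for slc2a1a, 0.037 for sparc, −0.050 for cfap20, −0.034 for sycp3 and −0.032 for foxl2a. The cause of these turns was not tested. Signal limits the rest: 59.8% to 66.7% of targets lay above the random probes on an array.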

Other observations

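Chosen after the data were seen were the tests on genome neighbours, the globin values with arrays left out or with ba1l, the counts over other splits of the arrays, and the values for single arrays, inner ear genes and hox genes.

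Single brains differed from each other in genes of particular tissues and body regions. A gap of at least 8-fold between neighbouring values, when the 6 arrays were sorted, was present in 55 targets, and in 0 of them did it part lead from control. Control replicate 1 alone was high in 31 of these. Besides the pituitary hormones, it held high values for inner ear and cartilage genes. Of 17 such genes above the random probes on at least 1 of the other arrays, 10 were highest on control replicate 1, where their median deviation was 1.76, against −0.62 to −0.24 on the other arrays. The collagen gene col9a1b stood at 15.11 there and at 10.54 to 10.86 elsewhere, the inner ear protein gene coch at 15.15 and 9.38 to 11.85, and s100t, not above the random probes on the other arrays, at 15.05 and 9.19 to 10.19.

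Lead replicate 2 was low in hox genes, which mark the hindbrain and spinal cord along the body axis. Of 22 hox genes above the random probes on at least 1 array, 20 were lowest on lead replicate 2, with a median deviation of −1.66, and of the 20 above the random probes on an array other than control replicate 1, 17 were highest on that array. For hoxb5b the value was 7.23 on lead replicate 2 and 11.43 to 13.12 on the others, and for hoxc5a 8.16 and 11.86 to 14.00. Between 2 and 4 arrays were high in 10 of the 55 targets, across the groups. The polyamine regulator gene oaz1a read 15.15 and 14.46 on control replicate 3 and lead replicate 2 and 7.69 to 8.16 on the other 4 arrays.

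Higher cell cycle genes in lead brains, and higher pax6b and pax6a, which cerebellar neurons also express, could come from a larger share of cerebellum in the dissected tissue, a site of lasting neurogenesis in fish. The list's median of 0.31 does not rest on 1 array, since it was 0.20 at the lowest, without lead replicate 2, above the 0.15 set as the limit. Of 25 measured cerebellum genes, 7 of them in another list too, 17 were higher and the 8 with an unadjusted p under 0.05 were all higher, among them barhl1a (1.74) and slc17a7a (1.1), which like pax6b lay nearest to the lead arrays on control replicate 2. The 12 with a control intensity above 10000 went from calb2a (−0.24) to zic5 (0.82), 5 of them lower. The list median of 0.18 met the limit of 0.15. Its 95% bootstrap interval over genes, from −0.08 to 0.61, includes 0, which leaves the matter open. Such an interval takes genes as independent and does not measure the spread between brains. For ovary tissue the list median was 0.079 (−0.08 to 0.20), an interval that reaches past 0.15 and does not decide. Without the gene shared by both lists, a version chosen afterwards, the median was 0.07 (−0.12 to 0.13). Ovary tissue was also predicted to bring its genes above the random probes. Of 18 such genes, 12 were higher, but 16 lay under the random probes on every array. The level of these 16 genes argues against ovary tissue. Lead exposure itself stays open as a cause.

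Lower erythrocyte genes in lead brains may reflect less blood left in the dissected tissue. The 3 measured adult globins of the list written beforehand had a median of −0.59 (hbaa1, at intensities of 39937 and 26609; hbaa2 −1.48; hbba2 under the random probes), beyond the limit of −0.47, set from the red cell genes without globins, and with the abundant ba1l added the median was −0.69. The median deviation of the 3 was 0.34, 0.17 and 0.42 in the controls and 0.33, −0.98 and −0.23 in the lead brains. Without lead replicate 2 hbaa1 was at −0.24, hbaa2 at −0.91 and ba1l at −0.65. The median of the 3 was then −0.473, only just beyond the limit of −0.466, and −0.561 with ba1l added. That −0.473 is the value of hbba2, under the random probes on every array, while the abundant hbaa1 fell short of the limit. The limit itself was set with lead replicate 2 included, so this median cannot decide. The fall was thus smaller without 1 array, and the explanation stays open. The drop of the whole list was not due to 1 array alone, as the list's median nearest 0 was −0.56, without lead replicate 2, against a limit of −0.34. A difference in the red cells themselves after lead stays open, untested.

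The targets with the smallest p may lie together on the genome, as a difference in haplotype between the families of the groups would have it. Among the 200 with the smallest p, 21 neighbouring pairs lay within 100000 bases, where 10000 random sets had a median of 4 and an upper limit of 8, all counted apart for OTTDART and other targets, so neighbours across these are missed. When pairs that overlap or share a name were left out, 8 remained, against a median of 3 and an upper limit of 7. The authors' table, which names altered targets only, gives 2 of the 8 a shared name and leaves 6 (SD 0.198 against 0.223), so several targets of 1 gene as the cause of the excess stays open. In 100% of the 8 pairs both members went the same way, their spread was no smaller than that of the others (SD 0.214 against 0.212), and a haplotype difference cannot be told apart from shared regulation of neighbours, since the spread turns with the naming and the labels give no families.

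The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. For targets past adjustment the real value was 0 and the highest other 3, with 10 of 10 splits as large, and the same values held for probes, with 10 of 10. At an unadjusted p under 0.05 the real split gave 1696 targets and the highest other 3534, from control replicate 1 grouped with lead replicates 1 and 3, with 6 of 10 as large. For gene lists the real value was 10 and the highest other 9, with 1 of 10 as large. The other splits gave 8, 1, 6, 9, 4, 7, 0, 7 and 6 lists at the preset correlation. List calls at this setting thus came with most groupings of these arrays, whatever the exposure. With an estimated correlation or with fry every split gave 0.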
